A study of Mus musculus with 27 samples.

How the data were processed

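The deposited table held counts, whole numbers from 0 per mouse gene, for 27 libraries of CD8+ T cells from MC38 tumours, with 1 column per library and no normalisation applied by the authors. It listed 47729 Ensembl gene IDs. DESeq2 1.26.0 is named in the processing notes without a role, and the aligner, the counting tool, the genome build and the annotation are not given in the sources used here. Symbols came from the GENCODE M21 name table, which named 47224 of the IDs and left 505 without a symbol. Each column was matched to its group by the description in the labels, and no column was left unmatched.

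Libraries were grouped by treatment, PD-1 gate and KLRG1 gate as the labels give them, in 6 groups. The labels attach the replicate number to the treatment and repeat it across gates, without stating whether equal numbers share a mouse. The column names run consecutively through the libraries of the same treatment and number. The descriptions carry an RNA-number suffix in replicate 4 of Iso and replicates 4 and 5 of Tri, so that the libraries fall into 2 name series, and the series was a term in the model. The groups, tests, 20 gene lists, named-gene rule and most alternatives were fixed before the data were examined.

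Genes were kept by edgeR's filterByExpr at a minimum count of 10, which left 14059. Libraries were scaled with TMM, and a robust quasi-likelihood model was fitted with edgeR 4.0.16 in R 4.3.3 to all 27 libraries, with a mean per group and the name series. There were 7 comparisons of groups and 2 interactions, each tested with the quasi-likelihood F test. P-values were adjusted by Benjamini-Hochberg, and genes under 0.05 were called. Standard errors are the log2 fold change divided by the square root of F. Expression is given as CPM with the SD between libraries.

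The genes named were chosen by a rule. It took the genes of the sort (Klrg1, Pdcd1, Cd8a, Cd3e and Ptprc), the 8 largest changes in each direction among called genes with at least 10 CPM in the higher group and libraries that did not overlap, without T cell receptor or immunoglobulin segments, and up to 4 members of each list with the smallest p. Some genes that the rule names are not reported here. For interactions up to 5 genes per direction were taken, with at least 10 CPM in 1 group. Where a group had no count, the fold is a lower bound against a floor of 3 counts over the group. Floors cover counting error only. Fitted folds of such genes depend on the prior count, and list medians were also computed with them at their bound.

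Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 20 lists within a comparison, and again with an estimated correlation. All 315 listed members were found in the table. The lists covered cytotoxic molecules, terminal effector genes, stem-like and memory genes, inhibitory receptors, tissue residency, homing, proliferation, interferon-stimulated genes, NK receptors, early antigen-receptor response, cytokine receptors, costimulatory receptors, glycolysis, oxidative phosphorylation, heat shock, and markers of myeloid, B, CD4 or regulatory T, NK or innate-like, and tumour or stromal cells. Agreement between comparisons that share no library was described by correlations across genes and by shared calls.

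Library measures were compared with 2-sided exact permutation tests, adjusted over 77 tests. Well-expressed genes for the share without a count had a median of at least 20 CPM over the libraries. Library totals ran from 6991521 to 26284630 counts in 26 libraries and were 93198 in Iso PD1-KLRG1+ replicate 3.

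Alternatives were median-ratio (RLE) scaling, no count filter and a minimum count of 50, no name-series term, each name series alone, only the groups compared, a replicate block, DESeq2 1.42.0, limma-voom with the animal number as a random block, fry, and leaving out each library. Alternatives added after the data had been seen were genes with a mean of at least 50 CPM, the number of genes detected as a covariate, limma-voom with sample weights, leaving out 3 libraries that stand apart (Iso PD1-KLRG1+ replicates 3 and 4 and Tri PD1-KLRG1- replicate 5), and leaving out the 4 Iso PD1-KLRG1+ libraries. The procedure was also tested on simulated data with known changes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.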

Results

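The data were RNA-seq counts of 27 libraries of CD8+ T cells taken from MC38 tumours, which derive from a mouse colon adenocarcinoma line. Digested tumours were stained for CD45, CD3, CD8, PD-1 and KLRG1, and CD8+ cells were sorted by the last 2 of these markers. PD-1, encoded by Pdcd1, is an inhibitory receptor of activated T cells, and KLRG1 is a receptor found on late effector T cells and NK cells. The labels name 2 treatments, Iso and Tri. Iso stands for an isotype control, and Tri is the combined immunotherapy that the series text abbreviates as TCT, whose parts are not given in the sources used here. There were 5 libraries of Tri PD1+KLRG1+, 5 of Tri PD1+KLRG1-, 4 of Tri PD1-KLRG1+, 5 of Tri PD1-KLRG1-, 4 of Iso PD1-KLRG1+ and 4 of Iso PD1-KLRG1-. The question stated for the series was which genes mark the CD8+ populations that appear under the treatment. PD1+ cells were sequenced under Tri alone, so the treatment could be compared in PD1- cells only.

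Library totals ran from 6991521 to 26284630 counts, except for replicate 3 of Iso PD1-KLRG1+, which held 93198. The Iso PD1-KLRG1+ libraries stood apart from all others in how few genes they held. Of the 6951 genes with a median of at least 20 CPM (counts scaled to a common library total), 16.29% ± 9.08 (SD, n = 4) had no count in an Iso PD1-KLRG1+ library, against 0.0360% ± 0.0432 (n = 4) in Iso PD1-KLRG1- and 0.259% ± 0.306 (n = 4) in Tri PD1-KLRG1+. With each library thinned to 93198 counts, the Iso PD1-KLRG1+ libraries held 6526 ± 492.5 genes, Tri PD1-KLRG1+ 8582 ± 264 and Iso PD1-KLRG1- 9147 ± 135. Both differences had a 2-sided exact permutation p of 0.0286, the smallest that 4 against 4 libraries allow, and a Benjamini-Hochberg p of 0.122 over the 77 library measures tested. Replicate 4 of this group also held 9262 CPM of myeloid marker transcripts and 3650 CPM of tumour and stroma marker transcripts, while its 3 other libraries held at most 1233 and 580.1 CPM.

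**Figure D1:**
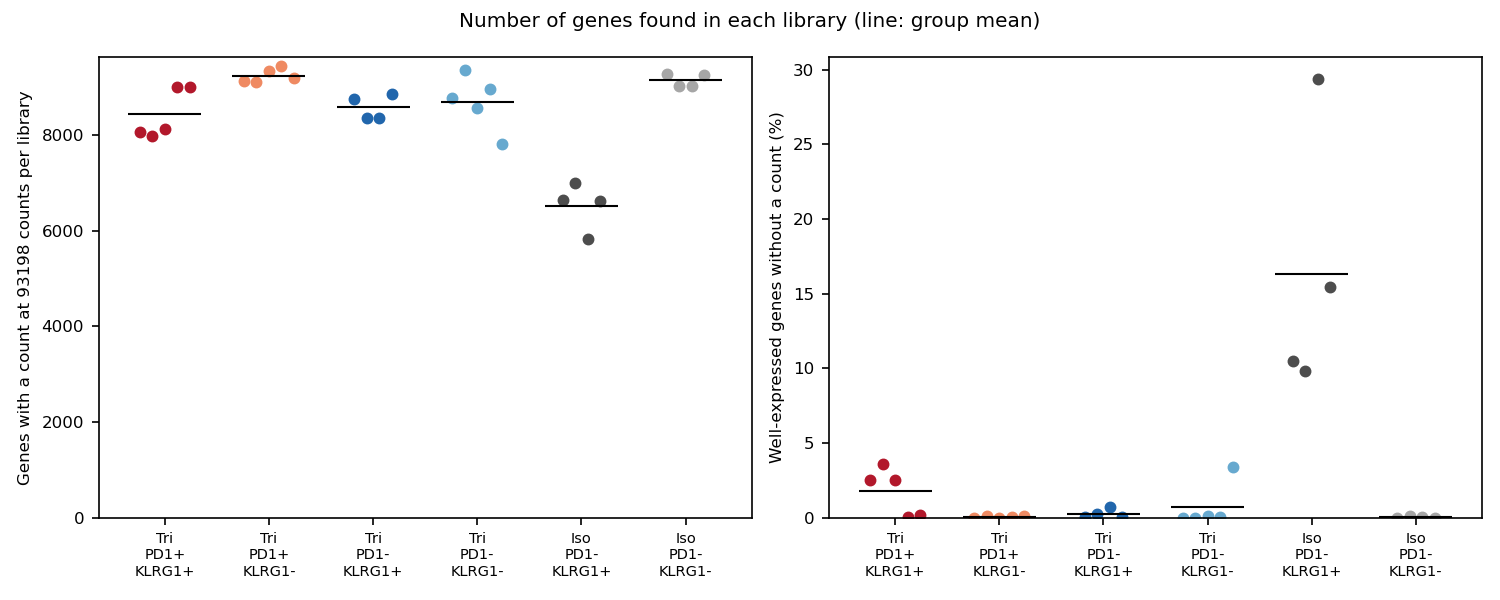
Left, genes with at least 1 count after thinning each library to 93198 counts; right, percent of 6951 well-expressed genes without a count; points are libraries, lines are group means. The 4 Iso PD1-KLRG1+ libraries hold at most 6996 genes at equal counts and lack at least 9.81% of the well-expressed genes.

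The transcripts of both sort markers followed the gates. Klrg1 (ENSMUSG00000030114) was at 254 ± 70.8 CPM in Tri PD1-KLRG1+, 210.3 ± 72.2 in Iso PD1-KLRG1+ and 92.0 ± 43.8 in Tri PD1+KLRG1+ libraries. In the KLRG1- groups it was at 19.6 ± 12.5 CPM (Tri PD1-), 5.07 ± 2.84 (Tri PD1+) and 1.77 ± 2.08 (Iso PD1-). Pdcd1 (ENSMUSG00000026285) was at 935 ± 279 CPM in Tri PD1+KLRG1+ and 1233 ± 228 in Tri PD1+KLRG1- libraries, and its mean lay between 57.3 and 119 CPM in the PD1- groups. These genes were used to define the groups, so their differences between gates are a check of the labels and no finding. Within the PD1-KLRG1- gate, Klrg1 was higher under Tri than under Iso (3.33 ± 0.78, adjusted p = 0.0359). Each of the 5 Tri libraries lay above each of the 4 Iso libraries, but the call held in only 2 of 9 fits that left out 1 library (up to 0.163, without Iso PD1-KLRG1- replicate 2). The edgeR p-values below rest on a spread per gene shared by all 27 libraries, which need not match that of the groups compared. Correlations of log2 CPM between replicates were 0.54 to 0.66 in Iso PD1-KLRG1+ and at least 0.73 in the other groups. All p-values refer to these samples, since the labels do not state that each library comes from a separate mouse.

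The first comparison asked how treatment altered PD1-KLRG1- cells. Under Tri these cells held more transcripts of effector molecules. Gzmb (ENSMUSG00000015437), the granule protease granzyme B, was at 1960 ± 280.3 CPM under Tri (n = 5) and 549.6 ± 19.9 under Iso (n = 4), a log2 fold change of 1.84 ± 0.20 (SE, adjusted p = 3.32e-06). Gzmk, another granzyme, rose by 2.63 ± 0.33 (544 ± 188 against 93.1 ± 25.7 CPM, adjusted p = 4.37e-05), and Fasl, a death receptor ligand, by 1.80 ± 0.25 (adjusted p = 0.000208). Klrk1, which encodes the activating receptor NKG2D, reached 942 ± 100.1 CPM against 287 ± 83.6 (log2 fold change 1.67 ± 0.18, adjusted p = 3.25e-06). Serpinb9, an inhibitor of granzyme B, rose from 59.3 ± 16.1 to 286 ± 45.8 CPM (log2 fold change 2.25 ± 0.23, adjusted p = 3.25e-06). In each of these genes every Tri library lay above every Iso library.

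Among 17 cytotoxic effector molecules, 3 rose and 1 fell in the Tri PD1-KLRG1- cells, and 6 rose when adjusted over the list alone. The list as a whole was higher than other genes (camera, median log2 fold change 0.62, adjusted p = 1.49e-07). Of 18 terminal effector genes, 17 were higher under Tri, 4 of them past the threshold and 10 when adjusted over the list alone (list median 0.81, adjusted p = 2.48e-12). They included Bhlhe40, a transcription factor of activated T cells, at 1.80 ± 0.25 (adjusted p = 0.000208), and Id2, a regulator of effector differentiation, at 1.20 ± 0.24 (adjusted p = 0.012; 0.0584 without Iso PD1-KLRG1- replicate 2). Costimulatory receptors were higher as a list, although none of the 11 members passed singly (median 0.34, adjusted p = 0.000181). These 3 lists kept their calls with an estimated correlation between genes (adjusted p = 0.000601, 2.5e-05 and 0.012).

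The chemokine receptor genes Cxcr6 and Ccr2 were higher in Tri PD1-KLRG1- cells. Cxcr6, a receptor of tissue-resident T cells, was at 1589 ± 99.8 CPM against 570.5 ± 127 (log2 fold change 1.46 ± 0.20, adjusted p = 0.000188). Ccr2 was at 524 ± 229.8 CPM against 67.5 ± 45.0 (adjusted p = 0.0118), a call that ended without Iso PD1-KLRG1- replicate 2 (0.0918) or replicate 3. The inhibitory NK receptor gene Klrc1 was at 764 ± 184 CPM against 181 ± 44.7 (2.07 ± 0.29, adjusted p = 0.000253). Homing receptors and egress had 13 of 22 members with a positive value and 4 called higher (median 0.26, mean -0.14, test upward with adjusted p = 0.00482, but adjusted p = 0.163 with an estimated correlation). Further lists were called upward with the fixed correlation and not with an estimated correlation: inhibitory receptors (median 0.71, adjusted p = 9e-04, then 0.0798 with an estimated correlation), glycolysis (0.33, 0.000117, then 0.0635), interferon-stimulated genes (0.39, 0.00258, then 0.0832), early antigen-receptor response (0.32, 0.00845, then 0.0635) and cytokine receptors (0.40, 0.00418, then 0.0635). The stem-like and memory program was lower (median -0.64, adjusted p = 0.0121, but adjusted p = 0.0832 with an estimated correlation), with 4 of 18 members above 0.

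Genes lower under Tri included Rps19, a ribosomal protein gene (693 ± 217 against 2174 ± 998 CPM, log2 fold change -1.49 ± 0.23, adjusted p = 0.000878), and Junb, an AP-1 transcription factor (-1.16 ± 0.19, adjusted p = 0.00218). Fbln2, an extracellular matrix gene, had no count in the 5 Tri libraries and 10.0 ± 5.88 CPM under Iso, at least 230-fold lower (adjusted p = 0.00734). Fcer1g, a signalling chain of Fc receptors in myeloid and NK cells, fell by 3.48 ± 0.71 (adjusted p = 0.0123; 0.0534 without Tri PD1-KLRG1- replicate 2). Lists of other cell types moved with the treatment. Myeloid markers had 14 of 15 members with a negative value, 1 called and 5 when adjusted over the list alone (median -2.52, adjusted p = 9.07e-06, but adjusted p = 0.0709 with an estimated correlation), tumour and stroma markers had a median of -1.37 (1.64e-05, then 0.0632) and NK and innate-like markers of -1.91 (0.0118, then 0.0632). Summed myeloid marker transcripts were at 455.7 ± 159 CPM under Tri and 1850 ± 1501 under Iso (exact permutation p = 0.00794, the smallest possible, Benjamini-Hochberg 0.102). Iso replicate 4 raised that mean, with 4071 CPM against 902.7 to 1455 in the other Iso libraries. Mitochondrial transcripts were at 0.8197% ± 0.306 and 2.46% ± 1.05 (the same p). The dissociation and heat-shock list was lower too (median -0.47, adjusted p = 0.028, but adjusted p = 0.179 with an estimated correlation), a call that ended without Iso PD1-KLRG1- replicates 3 (0.0624) or 4 (0.134) or Tri PD1-KLRG1- replicates 1 (0.0606) or 4 (0.0508). No call was made for tissue residency (adjusted p = 0.884), NK receptors (0.724), proliferation (0.248), oxidative phosphorylation (0.988), B cell markers (0.368) and CD4 or regulatory T cell markers (0.345).

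In total, 37 genes rose and 76 fell between Tri and Iso PD1-KLRG1- cells (edgeR, of 14059 tested; 1125 had an unadjusted p under the threshold, where chance gives 703). Of the 76, 47 were ribosomal protein genes and 3 translation elongation factors, so most falling calls belong to genes that move together. Ribosomal protein genes held 6.32% to 11.62% of counts in Iso libraries without the name suffix and 2.99% in Iso replicate 4. The total of 113 became 28 without Iso PD1-KLRG1- replicate 2, 54 without its replicate 3, and 70, 49, 73 and 60 without Tri PD1-KLRG1- replicates 1, 2, 3 and 4. Libraries without the name suffix alone gave 60 genes and those with it none, and a fit without the name-series term 68. With the number of genes detected as a covariate 29 rose and 13 fell. Limma-voom with sample weights called 364 higher and 734 lower, DESeq2 373 in total, limma-voom with an animal block 286 and edgeR without a count filter 251. Among genes with a mean of at least 50 CPM 172 were called, without 3 libraries that stand apart 217, and without the Iso PD1-KLRG1+ libraries 302.

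In PD1-KLRG1+ cells the same question met Iso libraries with few genes. Cd69, an early activation marker that also retains cells in tissue, was at 374 ± 45.4 CPM under Tri (n = 4) and 91.5 ± 43.8 under Iso (n = 4), a log2 fold change of 1.94 ± 0.29 (SE, adjusted p = 0.000141). Cxcr6 rose by 1.06 ± 0.20 (1243 ± 121 against 589 ± 215 CPM, adjusted p = 0.00191), and Il7r, the receptor for a survival cytokine of memory cells, by 3.38 ± 0.70 (139.5 ± 86.6 against 11.4 ± 13.1 CPM, adjusted p = 0.0039). Ctla4, an inhibitory receptor gene, was at 50.6 ± 7.04 CPM under Tri without any count under Iso, at least 576-fold higher (adjusted p = 3.18e-07). Srf, a transcription factor, and Itgb3, an integrin chain, were likewise without a count under Iso and at 58.6 ± 9.94 and 66.3 ± 20.8 CPM under Tri (adjusted p = 3.18e-07 and 9.73e-05). Of the 768 genes called higher, 391 had no count in any of the 4 Iso libraries, the group in which 16.29% of well-expressed genes had none.

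Lower in Tri PD1-KLRG1+ cells were genes of myeloid and stromal cells. Cd74, the invariant chain of antigen-presenting cells, was at 39.2 ± 15.1 CPM against 1007 ± 1673 (log2 fold change -4.15 ± 0.82, adjusted p = 0.00261), and Lyz2, lysozyme of myeloid cells, at 18.2 ± 10.7 against 540.2 ± 837 (-4.16 ± 0.92, adjusted p = 0.00695). Myeloid markers had 3 of 15 members called lower and 6 when adjusted over the list alone (median -4.15, unchanged with members without counts at their bound, adjusted p = 1.87e-06). Tumour and stroma markers had a median of -6.24 (-6.31 with bounds, adjusted p = 8.78e-07). With an estimated correlation neither call held (adjusted p = 0.218 and 0.107). Much of this lay in Iso replicate 4, with 9262 CPM of summed myeloid markers against 1233, 928.5 and 246.8 in the other Iso libraries. Iso replicate 3, at 246.8, lay below every Tri library (292.1 to 370.7). For tumour and stroma markers its 42.92 CPM lay within the Tri range (34.94 to 97.42). Cx3cr1, a chemokine receptor of late effector cells, fell by 1.81 ± 0.46 (adjusted p = 0.0194; 0.0717 without Tri PD1-KLRG1+ replicate 2, and also lost without its replicate 3).

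The stem-like and memory program was higher under Tri in PD1-KLRG1+ cells, with 5 of 18 members called and 6 when adjusted over the list alone (median 1.29, adjusted p = 0.0483, but adjusted p = 0.256 with an estimated correlation). Its members included Cd28, a costimulatory receptor gene (1.14 ± 0.26, adjusted p = 0.00929), and Id3, a factor of memory precursors, which had no count under Iso and 9.21 ± 3.22 CPM under Tri. Inhibitory receptors were higher as a list (2 of 19 called higher and 1 lower, median 0.92, 0.90 with bounds, adjusted p = 0.0149, but adjusted p = 0.256 with an estimated correlation). CD4 and regulatory T cell markers were higher too (median 2.06, 2.27 with bounds, adjusted p = 0.0483, but adjusted p = 0.256 with an estimated correlation). The 1 member called, Ctla4, is also in the inhibitory receptor list. The heat-shock list was lower by its test (median -0.27, mean 0.16, adjusted p = 0.0151, but adjusted p = 0.256 with an estimated correlation), and so was the homing list (2 called higher and 1 lower, median -0.06, mean 0.20, adjusted p = 0.0483, but adjusted p = 0.375 with an estimated correlation). Both tests are against other genes, and the median log2 fold change of all genes was 0.34 here. Neither list is thus shown to fall as a whole. Leaving out Iso PD1-KLRG1+ replicate 4 ended 4 of the 7 list calls, with adjusted p = 0.3 for the stem-like, 0.0682 for the inhibitory receptor, 0.124 for the heat-shock and 0.347 for the CD4 list. The CD4 call ended without any 1 of the 8 libraries and the homing call without any 1 of 7 (up to 0.241, without Iso PD1-KLRG1+ replicate 1). The stem-like call also ended without Iso replicate 2 (0.0533) and Tri replicates 1 (0.0581) and 4 (0.0871), and the heat-shock call without Iso replicate 2 (0.11) and Tri replicate 4 (0.0542).

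Across all genes, 768 rose and 87 fell between Tri and Iso PD1-KLRG1+ cells (3120 with an unadjusted p under the threshold). The total of 855 became 447 with the number of genes detected as a covariate, 179 among genes with a mean of at least 50 CPM, 497 in libraries without the name suffix and 2107 in those with it. It became 1947 with DESeq2, 1404 without 3 libraries that stand apart and 0 in a fit of these 8 libraries alone. Limma-voom with sample weights called none higher and 5 lower (1371 with an unadjusted p under the threshold), and median-ratio scaling 607 higher and 136 lower. Median-ratio scaling lowered the log2 fold changes of all genes by a median of 0.19 here, raised them by 0.15 in the KLRG1 comparison of Iso cells and by 0.10 in the PD1 comparison of KLRG1+ cells, and lowered them by 0.17 in the interaction of KLRG1 with treatment.

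The changes under Tri in KLRG1+ and KLRG1- cells, which share no library, shared 10 genes higher and 5 lower, where independent lists would share 2.02 and 0.47, and no gene was called in opposite directions. Some lists were called in opposite directions, with the fixed correlation only. The stem-like and memory program was higher in KLRG1+ (median 1.29) and lower in KLRG1- cells (-0.64). Homing was lower by its test in KLRG1+ (median -0.06) and higher in KLRG1- cells (0.26). The log2 fold changes correlated weakly across 14059 genes (Pearson r = 0.0928, Spearman rho = 0.0821) and at 0.237 and 0.156 across 4438 genes with a mean of at least 50 CPM (genes are not independent replicates). Id2, Serpinb9, Klrk1, Klrc1 and Cxcr6 were among the shared higher genes, and Cd74, Fcer1g, Junb, Col1a1 and Fbln2 were those shared as lower, names taken after the overlap was seen.

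The difference between the 2 treatment effects was tested as an interaction of KLRG1 with treatment in PD1- cells. It was called in 505 genes, 479 with a more positive KLRG1 effect under Tri and 26 with a more negative one. Srf was at 58.6 CPM in Tri PD1-KLRG1+, 42.1 in Tri PD1-KLRG1-, 59.4 in Iso PD1-KLRG1- and 0 in Iso PD1-KLRG1+ libraries, and Abcc4, a membrane transporter gene, was at 35.6, 6.81, 13.8 and 0. Il1r2, a decoy receptor for interleukin-1, went the other way, with 0, 18.9, 1.503 and 11.1 CPM. The 505 genes became 119 with genes detected as a covariate, 57 among genes with a mean of at least 50 CPM, 277 in a fit of these groups alone, 298 in libraries without the name suffix and 1662 in those with it. Limma-voom with sample weights called none (1235 with an unadjusted p under the threshold), and median-ratio scaling gave 399 and 59. DESeq2 called 1264, limma-voom with an animal block 240, and edgeR 277 with a replicate block and 1090 without 3 libraries that stand apart. Leaving out Iso PD1-KLRG1- replicate 2 gave 318, and leaving out Iso PD1-KLRG1+ replicates 1 and 2 gave 798 and 866.

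Genes called between PD1+ and PD1- cells of the Tri tumours in both KLRG1 gates had the same direction in both. In KLRG1- cells, Gzma, a granzyme of circulating effectors, was at 11.6 ± 8.58 CPM in PD1+ (n = 5) and 461 ± 124 in PD1- libraries (n = 5), a log2 fold change of -5.65 ± 0.80 (SE, adjusted p = 8.3e-05). Prf1, the pore-forming perforin, went up by 2.12 ± 0.26 (936 ± 216 against 215 ± 42.5 CPM, adjusted p = 2.09e-05), and Gzme, another granzyme, was at 121 ± 27.4 CPM without any count in PD1- cells, at least 2780-fold higher (adjusted p = 4.87e-05). Tnfrsf9, the costimulatory receptor 4-1BB, rose by 2.69 ± 0.32 (1317 ± 328 against 209 ± 27.2 CPM, adjusted p = 1.55e-05) and the inhibitory receptor gene Lag3 by 3.03 ± 0.59 (93.0 ± 17.8 against 11.2 ± 4.51 CPM, adjusted p = 0.00366). Lef1, a transcription factor of naive and memory precursor cells, fell by 3.11 ± 0.33 (21.9 ± 10.2 against 182 ± 30.7 CPM, adjusted p = 3.25e-06).

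Homing receptors were lower as a list in PD1+KLRG1- cells. Of 22 members, 9 fell and 1 rose, or 12 and 3 when adjusted over the list alone, and 5 had a positive value (median log2 fold change -1.51, adjusted p = 1.15e-12, and adjusted p = 0.00379 with an estimated correlation). S1pr1, the receptor by which lymphocytes leave tissue, was at 9.16 ± 9.83 CPM against 321 ± 28.9 (-5.20 ± 0.72, adjusted p = 5.75e-05). The chemokine receptor gene Cxcr3 was at 70.5 ± 13.4 against 622.9 ± 67.04 (-3.15 ± 0.38, adjusted p = 1.55e-05). Itgb7 (-2.91 ± 0.33) and Ccr2 (-3.58 ± 0.57) were also lower. Interferon-stimulated genes were lower, with 8 of 17 called and 14 when adjusted over the list alone (median -1.34, adjusted p = 6.54e-18, and 0.000226 with an estimated correlation). Rtp4 fell by 2.06 ± 0.27 (adjusted p = 4.07e-05) and Usp18 by 1.73 ± 0.31 (0.00152).

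The stem-like and memory program was lower in PD1+KLRG1- cells, with 3 of 18 members called (median -0.69, adjusted p = 1.27e-06, and 0.00379 with an estimated correlation). Inhibitory receptors were higher, with 4 of 19 called (median 1.23, adjusted p = 0.000735, but adjusted p = 0.156 with an estimated correlation), and glycolysis was higher (median 0.43, adjusted p = 0.0226, but adjusted p = 0.393 with an estimated correlation). The glycolysis call also ended without Tri PD1+KLRG1- replicate 1 (0.0571). Cytotoxic effector molecules split, 5 higher and 4 lower, with no call for the list (median -0.28, mean 1.14, adjusted p = 0.834): Gzmk and Ccl5, a chemokine of effector cells, fell by 2.31 ± 0.29 and 2.10 ± 0.28 while Prf1 and Gzme rose. Gzmb, chosen after its values were seen, fell by 0.72 ± 0.18 (1186 ± 325 against 1960 ± 280.3 CPM, adjusted p = 0.0329) and had no call in KLRG1+ cells (-0.52 ± 0.19, adjusted p = 0.221). Irf8, a transcription factor, was at 716 ± 131 CPM against 134 ± 43.0 (2.41 ± 0.31, adjusted p = 2.53e-05) and Il2rb, a chain of the interleukin-2 receptor, rose by 1.22 ± 0.19 (adjusted p = 0.000237). CD4 and regulatory T cell marker transcripts were at 352.8 ± 101 CPM in PD1+ and 205.8 ± 60.2 in PD1- libraries (exact permutation p = 0.0317, Benjamini-Hochberg 0.122).

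In total, 87 genes rose and 132 fell between PD1+ and PD1- cells of the KLRG1- gate (1339 with an unadjusted p under the threshold), and 31 of the 45 named genes called kept their call whichever 1 of the 10 libraries was left out. The total of 219 became 138 and 129 without Tri PD1+KLRG1- replicates 1 and 3, and 139 without Tri PD1-KLRG1- replicate 1. Libraries without the name suffix gave 91 genes, those with it 7, the fit of these 10 libraries alone 803, DESeq2 524 and limma-voom 624. Limma-voom with sample weights called 1154 higher and 864 lower, so that genes that rose were then in the majority. The balance also moved with the scaling, as genes that rose made up 39.7% of the calls with TMM and 47.9% with median-ratio scaling. EdgeR called 390 without a count filter, 341 without 3 libraries that stand apart and 538 without the Iso PD1-KLRG1+ libraries.

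Within the KLRG1+ gate, PD1+ cells held more transcripts of Prf1 and of the granzymes Gzmf and Gzmd. Prf1 was at 975 ± 106 CPM in PD1+ (n = 5) and 258 ± 80.9 in PD1- libraries (n = 4), a log2 fold change of 1.91 ± 0.28 (SE, adjusted p = 0.000558). Gzmf was at 1147 ± 399.5 CPM against 0.662 ± 1.32 (10.92 ± 1.41, adjusted p = 0.000447) and Gzmd at 289.5 ± 128 CPM against no count, at least 3800-fold higher (adjusted p = 0.00172). Gzma fell by 3.80 ± 0.74 (114 ± 81.4 against 1603 ± 734 CPM, adjusted p = 0.0059). S1pr5, a receptor for exit from tissue, had no count in PD1+ cells and 43.5 ± 27.9 CPM in PD1- cells, at least 1170-fold lower (adjusted p = 0.00556), and Id3 was at least 249-fold lower (no count against 9.21 ± 3.22 CPM, adjusted p = 0.000824). Tnfrsf9 rose by 1.87 ± 0.34 (adjusted p = 0.00291), Lag3 by 3.58 ± 0.67 (0.00406), Irf8 by 2.37 ± 0.33 (0.000558), Il2rb by 1.02 ± 0.20 (0.00683) and Tpi1, a glycolytic enzyme gene, by 1.00 ± 0.17 (0.00172).

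Of 17 cytotoxic molecules, 6 rose and 4 fell in PD1+KLRG1+ cells, 8 and 6 when adjusted over the list alone (median 0.19, adjusted p = 0.00016, and 0.0276 with an estimated correlation). Inhibitory receptors had 4 of 19 higher (median 1.28, adjusted p = 1.32e-06, and 0.0318 with an estimated correlation). Homing receptors had 5 of 22 lower, or 13 lower and 3 higher when adjusted over the list alone (median -1.48, adjusted p = 1.1e-06, and 0.0331 with an estimated correlation) and interferon-stimulated genes 3 of 17 lower, all 17 with a negative value (median -0.89, adjusted p = 1.32e-06, and 0.0305 with an estimated correlation). Cxcr3 fell by 1.81 ± 0.37 (adjusted p = 0.00903), Itgb7 by 1.88 ± 0.33 (0.00172), Cd69 by 1.53 ± 0.26 (0.00172) and Rtp4 by 1.73 ± 0.28 (0.00125). With the fixed correlation only, the stem-like program was lower (median -0.64, adjusted p = 0.0112, but adjusted p = 0.11 with an estimated correlation) and glycolysis higher (0.41, 0.00056, then 0.11). The early antigen-receptor response was higher as well (2 called higher and 1 lower, median 0.31, 0.0323, then 0.11), a call that ended without Tri PD1+KLRG1+ replicates 1 (0.0962) or 4 (0.0553), or Tri PD1-KLRG1+ replicate 4 (0.0821). Myeloid marker transcripts were at 657.3 ± 199.5 CPM in PD1+ and 329.9 ± 40.1 in PD1- libraries (exact permutation p = 0.0159, Benjamini-Hochberg 0.122) and CD4 or regulatory T cell marker transcripts at 328 ± 45.5 and 136 ± 12.8 (0.00794, the smallest possible, Benjamini-Hochberg 0.102). Their lists were not called (adjusted p = 0.273 and 0.0671), nor were NK receptors (0.548), B cell markers (0.406) or tissue residency (0.355).

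In total, 69 genes rose and 100 fell between PD1+ and PD1- cells of the KLRG1+ gate (1575 with an unadjusted p under the threshold), and 26 of the 41 named genes called kept their call whichever 1 of the 9 libraries was left out. Pdcd1 itself rose by 3.38 ± 0.84 (adjusted p = 0.0412) but lost its call in each of these 9 fits, up to 0.158 without Tri PD1-KLRG1+ replicate 4. Replicates 1 to 3 of Tri PD1+KLRG1+ stood apart with few genes (at most 8121 at equal counts, against 8351 to 8856 in Tri PD1-KLRG1+). The total of 169 was 170 with the number of genes detected as a covariate. It became 84 and 91 without Tri PD1-KLRG1+ replicates 1 and 4, 1 in libraries with the name suffix, 706 with DESeq2 and 370 with limma-voom. Sample weights gave 547, no count filter 334, and edgeR 359 without 3 libraries that stand apart and 475 without the Iso PD1-KLRG1+ libraries. Genes that rose made up 40.8% of the calls with TMM and 49.4% with median-ratio scaling, so the excess of falling genes depended on the scaling.

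**Figure D2:**
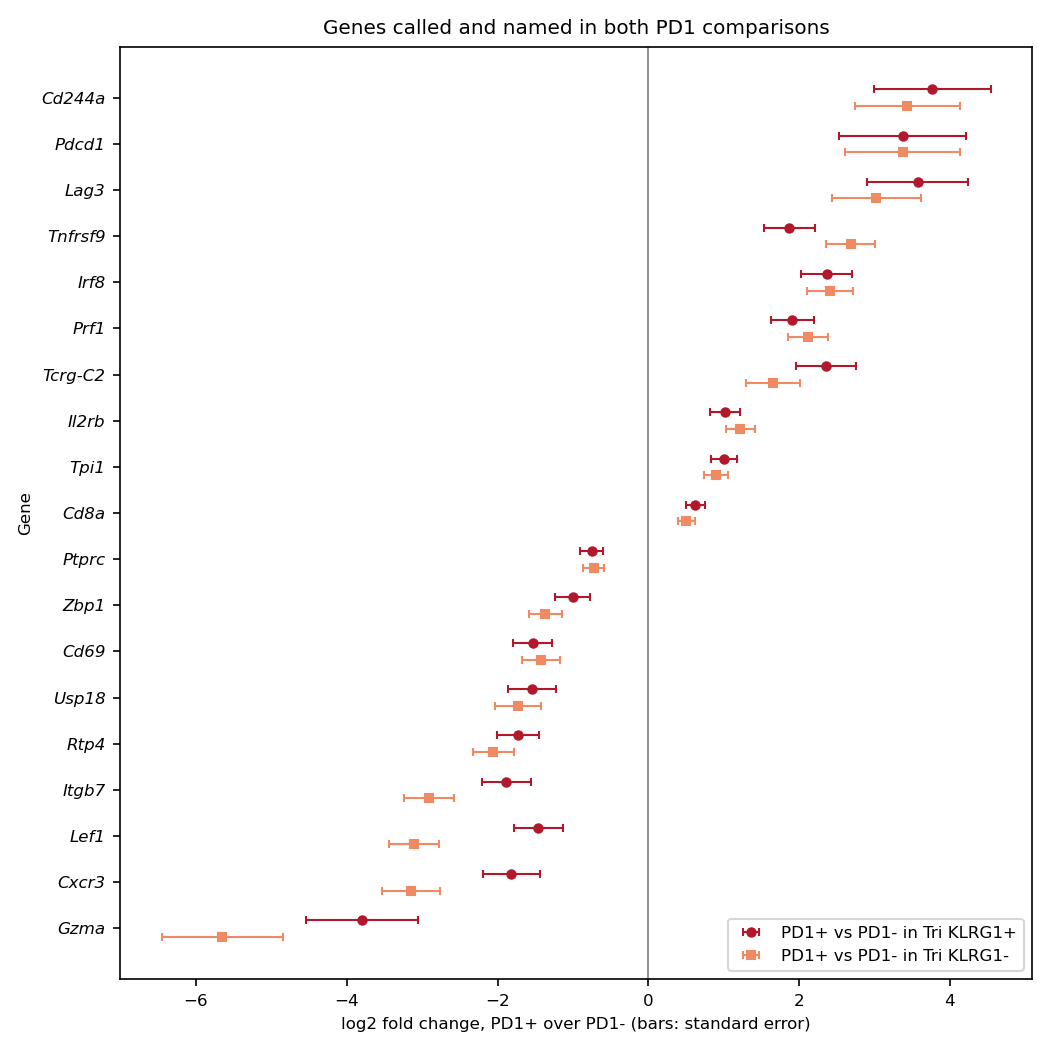
Log2 fold change of PD1+ over PD1- cells of Tri tumours for the genes named and called in both KLRG1 gates that had a count in each of the 19 Tri libraries; bars are standard errors. Each gene has the same sign in both gates, with Gzma lowest (fell by 5.65 in KLRG1- and by 3.80 in KLRG1+ cells).

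The PD1 effects in both gates shared 44 genes higher and 59 lower, where independent lists would share 0.427 and 0.939, and no gene was called in opposite directions. These comparisons share no library. Some list medians parted in sign, at 0.19 in KLRG1+ and -0.28 in KLRG1- cells for cytotoxic molecules and at -0.37 and 0.19 for NK receptors. Across 4438 genes with a mean of at least 50 CPM the log2 fold changes correlated at Pearson r = 0.742 and Spearman rho = 0.601, and across all 14059 genes at 0.351 and 0.361 (genes are not independent replicates). Cd8a was higher in PD1+ cells of both gates (0.63 ± 0.12 in KLRG1+ and 0.50 ± 0.11 in KLRG1- cells) and Ptprc, which encodes CD45, lower (fell by 0.75 ± 0.15 and by 0.72 ± 0.14). The Ptprc call in KLRG1+ cells ended without Tri PD1-KLRG1+ replicate 1 (adjusted p = 0.0771), and the Cd8a call in KLRG1- cells without Tri PD1+KLRG1- replicate 1, Tri PD1-KLRG1- replicate 1 or its replicate 4 (up to 0.0671).

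The interaction of KLRG1 with PD1 in Tri cells was called in no gene with edgeR (smallest adjusted p = 0.481), with 638 genes at an unadjusted p under the threshold where chance gives 703. DESeq2 called 197, limma-voom 4, or 5 with sample weights, and edgeR without a count filter 46, and leaving out Tri PD1-KLRG1+ replicate 1 gave 1. A call made in 1 KLRG1 gate and missed in the other is thus not shown to differ between the gates.

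KLRG1+ and KLRG1- cells were compared in 3 settings. Under Tri, PD1+KLRG1+ cells held more transcripts of effector molecules than PD1+KLRG1- cells. Gzmb was at 2337 ± 414 CPM (n = 5) against 1186 ± 325 (n = 5), a log2 fold change of 0.98 ± 0.18 (SE, adjusted p = 0.0217). Ccl5 was at 771 ± 370.3 against 240.4 ± 75.9 (1.56 ± 0.27, adjusted p = 0.0217) and Gzmk at 325 ± 121 against 104 ± 31.2 (1.56 ± 0.29, adjusted p = 0.0217). Id3 had no count in KLRG1+ and 2.361 ± 2.005 CPM in KLRG1- libraries, at least 63.8-fold lower (adjusted p = 0.0217). The 17 cytotoxic molecules were higher as a list, 14 of them positive and 5 called when adjusted over the list alone (median 0.42, adjusted p = 2.6e-09, and 0.000316 with an estimated correlation). All 20 proliferation genes were positive without a single call (median 0.84, adjusted p = 2.6e-09, but adjusted p = 0.335 with an estimated correlation). Homing receptors (median 0.21, 0.27 with bounds, adjusted p = 0.00365, then 0.456), oxidative phosphorylation (0.06, 0.0109, then 0.468) and glycolysis (0.10, 0.0394, then 0.477) were higher by small amounts, calls lost with an estimated correlation, whose adjusted p comes last. The homing call ended without Tri PD1+KLRG1+ replicate 4 (0.105), oxidative phosphorylation without its replicate 1 (0.0975), and glycolysis without Tri PD1+KLRG1+ replicates 1 (0.213), 2 (0.0754) or 4 (0.0833) or Tri PD1+KLRG1- replicates 4 (0.0689) or 5 (0.162). PD1+KLRG1+ libraries held 8441 ± 524 genes at equal counts against 9248 ± 144 (exact permutation p = 0.00794, the smallest possible, Benjamini-Hochberg 0.102). Replicates 1 to 3 of PD1+KLRG1+, which lack the name suffix, carried most of this difference. They held 7983 to 8121 genes and lacked 2.53% to 3.57% of the well-expressed genes. Replicates 4 and 5 held 9010 and 9015 genes and lacked 0.0288% and 0.173%, near the PD1+KLRG1- libraries (9117 to 9455 genes).

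Only 4 genes rose and 4 fell in this comparison (930 with an unadjusted p under the threshold). Those that rose were Gzmb, Ccl5, Gzmk and the sort gene Klrg1, and those that fell Id3 and, named after their values were seen, Marcks, Myl4 and Fam84b. The 8 genes became 0 without Tri PD1+KLRG1+ replicates 1, 2 or 3 or Tri PD1+KLRG1- replicates 1 or 3. They became 5, 1, 3 and 4 without Tri PD1+KLRG1+ replicate 5 and Tri PD1+KLRG1- replicates 2, 4 and 5. Each named call ended in at least 6 of these 10 fits (up to 0.138 for Gzmk, without Tri PD1+KLRG1- replicate 3). Libraries without the name suffix gave 41 genes, those with it none, DESeq2 205 and limma-voom 124. EdgeR called 50 without a count filter and 16 without 3 libraries that stand apart, and limma-voom with sample weights 23. With the number of genes detected as a covariate no gene was called.

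In PD1- cells under Tri, no gene was called between KLRG1+ (n = 4) and KLRG1- (n = 5) with edgeR (smallest adjusted p = 0.222, shared by Klrg1 at 3.65 ± 0.73 and Nrn1), and 675 genes had an unadjusted p under the threshold where chance gives 703. DESeq2 called 192, limma-voom with an animal block 4, edgeR without a count filter 39, limma-voom with sample weights 27, and leaving out Tri PD1-KLRG1+ replicate 1 or Tri PD1-KLRG1- replicates 3 or 4 gave 1. Lists moved where single genes did not. Of 18 terminal effector genes 17 were higher in KLRG1+ cells (median log2 fold change 0.50, adjusted p = 4.54e-07, and 0.000998 with an estimated correlation). Proliferation genes were all positive (median 0.57, adjusted p = 1.59e-05, but adjusted p = 0.476 with an estimated correlation) and interferon-stimulated genes all negative (-0.54, 9.73e-05, but 0.105 as the adjusted p with an estimated correlation). Of 18 stem-like and memory genes 15 were lower in KLRG1+ cells (median -0.35, adjusted p = 0.00392, but adjusted p = 0.105 with an estimated correlation). Tumour and stroma marker transcripts were at 62.6 ± 28.5 CPM in KLRG1+ and 153.4 ± 38.0 in KLRG1- libraries (exact permutation p = 0.00794, the smallest possible, Benjamini-Hochberg 0.102), without a call for their list (adjusted p = 0.507).

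Under Iso, PD1-KLRG1+ cells differed from PD1-KLRG1- cells in many genes, with the low number of genes in the KLRG1+ libraries on the same axis. Gzmb was at 3224 ± 964 CPM in KLRG1+ (n = 4) and 549.6 ± 19.9 in KLRG1- libraries (n = 4), a log2 fold change of 2.56 ± 0.21 (SE, adjusted p = 2.85e-08). Cx3cr1 was at 278 ± 156 against 39.6 ± 32.0 (2.90 ± 0.48, adjusted p = 0.000337) and Zeb2, a transcription factor of terminal effectors, at 90.8 ± 39.7 against 9.66 ± 6.04 (3.33 ± 0.64, adjusted p = 0.00129). Tbx21, which encodes the effector transcription factor T-bet, rose by 1.38 ± 0.25 (adjusted p = 0.000671), Gzmk by 2.37 ± 0.33 (5.15e-05) and Prf1 by 1.85 ± 0.29 (0.00023). Gzma was at 1514 ± 1656 CPM against 71.6 ± 25.2 (4.28 ± 0.83, adjusted p = 0.00156), and its highest library was replicate 1 at 3969 CPM. Il7r fell by 4.35 ± 0.73 (11.4 ± 13.1 against 270.4 ± 31.8 CPM, adjusted p = 0.000355). Ltb, a lymphotoxin gene, fell by 1.00 ± 0.18 (0.000631) and Ccr7, the lymph node homing chemokine receptor, by 4.61 ± 1.09 (0.00751). Id3 and Srf had no count in the KLRG1+ libraries and 137 ± 53.7 and 59.4 ± 20.5 CPM in the KLRG1- libraries, at least 1560-fold and 676-fold lower.

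Of 18 terminal effector genes, 9 rose in the Iso KLRG1+ cells and 10 when adjusted over the list alone (median 1.38, adjusted p = 6.24e-19, and 9.34e-07 with an estimated correlation). Stem-like and memory genes were all negative, 10 of 18 called (median -2.30, adjusted p = 1.14e-05, and 0.0092 with an estimated correlation). Cytotoxic molecules had 6 members higher and 2 lower (median 0.20, mean -0.23, test upward with adjusted p = 1.2e-06, and 0.00141 with an estimated correlation). Their median was 0.37 with median-ratio scaling and 0.84 with DESeq2. Homing receptors had 5 higher and 2 lower (median 0.39, mean -0.34, test upward with adjusted p = 1.2e-06, and 0.0434 with an estimated correlation). With fry, which tests a list against no change, homing had an adjusted p of 0.51. Camera tests a list against other genes, and the median log2 fold change of all genes was -0.52 here. The upward calls of the cytotoxic, homing and glycolysis lists are thus relative, and do not show that these lists rose as a whole. Proliferation genes were higher, 3 of 20 called (median 0.95, adjusted p = 9.52e-05, but adjusted p = 0.395 with an estimated correlation). Glycolysis was called upward with a median of -0.02, which turned to 0.14 under median-ratio scaling, and a mean of 0.34 (adjusted p = 0.000833, but adjusted p = 0.143 with an estimated correlation), a call that ended without Iso PD1-KLRG1+ replicate 4 (0.0506). CD4 and regulatory T cell markers were lower (median -2.35, -2.62 with bounds, adjusted p = 0.0309, but adjusted p = 0.143 with an estimated correlation). The 2 members called, Ctla4 and Ikzf2, are also in the inhibitory receptor list.

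In total, 174 genes rose and 1044 fell between the Iso KLRG1+ and KLRG1- cells (3744 with an unadjusted p under the threshold), and 490 of those that fell had no count in any of the 4 KLRG1+ libraries. With the number of genes detected as a covariate 72 rose and 154 fell, among genes with a mean of at least 50 CPM 168 rose and 323 fell, and without 3 libraries that stand apart 364 rose and 1585 fell. Libraries without the name suffix gave 157 higher and 770 lower, those with it 70 and 1924, and DESeq2 513 and 1813. Median-ratio scaling gave 275 and 927, and limma-voom with sample weights 13 higher and none lower (1552 with an unadjusted p under the threshold). KLRG1 effects in Tri and Iso PD1- cells, which share no library, correlated weakly across all genes (Pearson r = 0.0913, Spearman rho = 0.107), as did those in Tri PD1+ and Tri PD1- cells (0.117 and 0.0907). Across genes with a mean of at least 50 CPM these values were 0.212 and 0.224, and 0.153 and 0.156.

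**Figure D3:**
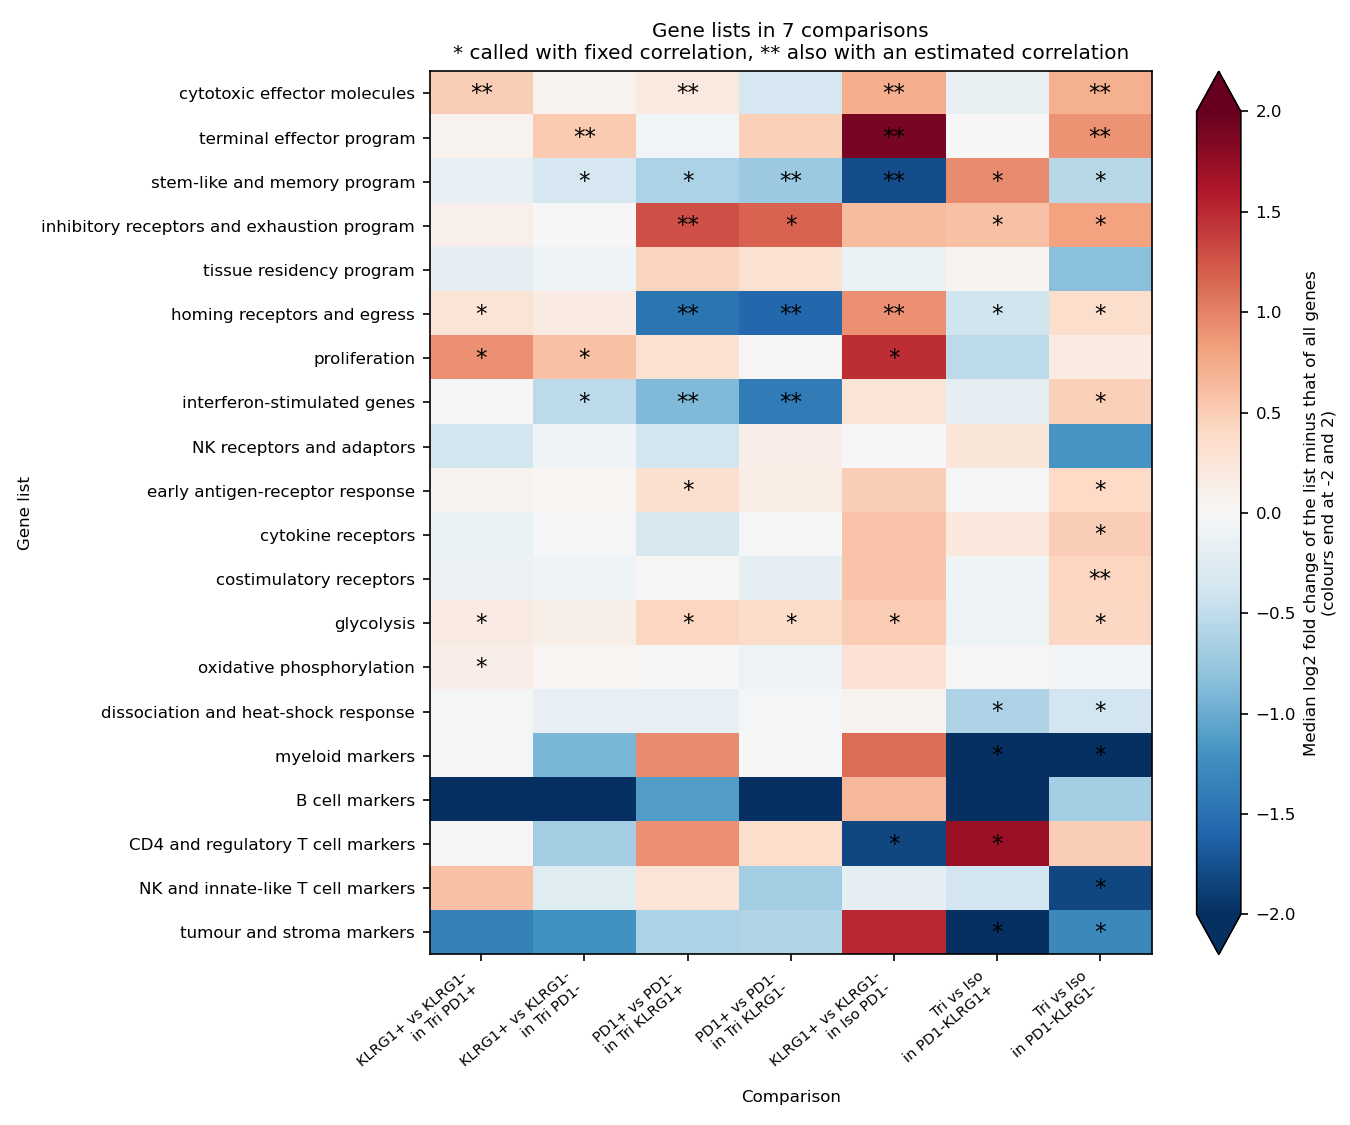
Median log2 fold change of each of 20 gene lists minus that of all genes in 7 comparisons; 1 star marks a camera call with the fixed correlation, 2 stars one that also held with an estimated correlation. Of 140 tests, 49 are called and 16 of these carry 2 stars, among them the homing and interferon-stimulated lists in both PD1 comparisons.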

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

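The tests on fewer counts, on a single library and on the 2 name series were chosen only after the result they measure was seen.

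A library stood apart from its group by Dixon's test in 25 of 262 sets of values, where chance gives about 1 in 20 for independent, normally distributed values. Many sets were untransformed CPM of genes chosen by their fold change, so an excess over chance is not shown. Where all libraries of a group but 1 had no count, the test is met by construction, as for Spp1, Nrp1 and Cd163l1 below. Iso PD1-KLRG1+ replicate 4 accounted for 6 of them, with 9262 CPM of myeloid markers (nearest other library 1233), 3650 CPM of tumour and stroma markers (580.1), Col1a1 at 1172 CPM (68.9), Cd63 at 606.6 (82.0), Gm28661 at 2626 (500.4) and Gm10925 at 1943 (580.6). In the same group replicate 3 held 5832 genes (8981) and replicate 1 had Gzma at 3969 CPM (1050). In Iso PD1-KLRG1-, replicate 4 had Ptprc at 2316 CPM (1549) and Pirb at 21.4 (7.29), and replicate 2 had ENSMUSG00000089672 at 23.9 (52.3).

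In Tri PD1-KLRG1+, replicate 3 had Vipr1 at 46.3 CPM (14.9), Eif2ak3 at 14.8 (56.1) and B cell markers at 14.5 (7.40), and replicate 1 had Spp1 at 0.693 and Nrp1 at 4.85 where the others had 0. In Tri PD1-KLRG1-, replicate 5 lacked 3.41% of well-expressed genes (0.101%), replicate 4 had Pirb at 0.0727 CPM and replicate 2 Col1a1 at 0.397, where the others had 0. In Tri PD1+KLRG1+, replicate 4 had 2.13% of counts on ribosomal protein genes (3.22%) and B cell markers at 10.2 CPM (2.80), replicate 3 CD4 and regulatory T cell markers at 248 CPM (338), replicate 5 Cd8a at 2186 CPM (1813) and replicate 2 Cd3e at 1278 CPM (1471). In Tri PD1+KLRG1-, replicate 3 had Cd163l1 at 0.490 CPM, where the others had 0.

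The interaction of KLRG1 with treatment in PD1- cells differed between the treatments in 505 genes. The fitted differences named by the rule were 14.23 for Ripply3, 13.67 for Ankrd52, 13.20 for Abcc4, 13.07 for Srf and 12.87 for Tff1, and -18.57 for Enpp2, -17.62 for Bok, -14.65 for Gm10163, -14.13 for Il1r2 and -12.28 for Apbb2. Groups without a count make these log2 values depend on the prior count. The interaction was called in at least as many genes in 4 of 100 splits of the libraries, the real one included. This lies under the limit of 5 in 100 fixed before, but only narrowly, so that chance is not excluded. The other 3 splits called 519, 587 and 788 genes, so the real grouping is not needed to reach 505, and why they do was not tested.

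In 6 of the 7 comparisons 1 split, the real one, called as many genes, a share under the limit fixed before. These shares were not adjusted over the comparisons. The splits also treat libraries as exchangeable, although some may share a mouse. The real count and the highest of the other splits were 8, Klrg1 itself included, and 3 for KLRG1 in Tri PD1+, 169 and 26 for PD1 in Tri KLRG1+, 219 and 0 for PD1 in Tri KLRG1-, and 113 and 23 for treatment in PD1-KLRG1- (100 splits each), and 1218 and 86 for KLRG1 in Iso PD1- and 855 and 94 for treatment in PD1-KLRG1+ (35 splits each). For KLRG1 in Tri PD1- and the interaction of KLRG1 with PD1, with 0 genes each and a highest other split of 1, all 100 of 100 splits had to reach as many, so these splits say nothing about chance. Chance also stays open for KLRG1 in Tri PD1+, where leaving out 1 library could bring the 8 genes to 0. It stays open for treatment in PD1-KLRG1+ too, where a fit of the compared libraries alone brought the 855 genes to 0.

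The first pattern weighed is the many genes called against Iso PD1-KLRG1+ libraries, 1044 lower than in Iso PD1-KLRG1- and 768 higher in Tri PD1-KLRG1+. The depth of the libraries is excluded as the whole cause, since at equal counts the highest Iso PD1-KLRG1+ library held 6996 genes, under the lowest of Iso PD1-KLRG1- (9027) and of Tri PD1-KLRG1+ (8351). Loss of transcripts unrelated to KLRG1 or treatment was tested in libraries outside each comparison. The 1044 genes had a median log2 fold change of -0.0822 between KLRG1+ and KLRG1- in Tri PD1- (matched sets -0.03 to 0.04, 58.7% on the same side), and the 768 genes one of 0.0579 between Tri and Iso PD1-KLRG1- (matched sets -0.21 to -0.09, 53.3% on the same side). The value for the 1044 genes argues against such loss as the whole cause. That for the 768 genes cannot decide, because its matched sets lie below 0. They can hold genes of myeloid and stromal RNA, which were lower under Tri and which the choice of the 768 left out. Both values are small, matched sets treat genes as independent, and loss of transcripts for a large part of these genes stays open beside a biological difference of the group.

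The second pattern is the lower myeloid markers in Tri than in Iso PD1-KLRG1- cells. A single library does not account for it, since without the highest Iso library the lowest held 902.7 CPM against at most 723.4 in Tri. RNA of myeloid cells in the Iso libraries may account for it, because a second list of 24 myeloid genes, written before its values were seen, had a median of -2.65 with 23 of 24 fitted values negative (matched sets reach -0.58). None of the 24 was called (smallest adjusted p = 0.205), and Il1b counts among the 23 although its mean was higher in Tri (5.61 against 4.39 CPM). Its abundant members were H2-Ab1 at 40.7 against 273 CPM, H2-Aa at 17.8 against 137.5, Ctss at 210.1 against 401 and Ctsb at 417 against 463, and Cd63 was already named in the other treatment comparison. The sort on CD45, CD3 and CD8 would remove most myeloid cells, and expression of these genes by T cells stays open.

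The third pattern is the lower ribosomal protein genes in Tri PD1-KLRG1- cells, with 47 of 88 called lower and none higher, and a median log2 fold change of -1.32. Between Tri and Iso PD1-KLRG1+ cells 0 of 88 were called, with a median of 0.23. These genes held 6.32% to 11.62% of counts in Iso PD1-KLRG1- libraries without the suffix. They held 2.99% in replicate 4 of that group and 1.88% to 3.08% in Iso PD1-KLRG1+ libraries. Poorer recovery of short transcripts in Tri was tested with genes matched on length and expression, which had a median of -0.0429 (-0.129 to 0.161 over bootstrap samples). Length was that of the longest annotated transcript, with a median of 1048 bases for ribosomal protein genes and 1109 for matched genes. The transcripts expressed can be shorter, so this test cannot decide the question. The name series does not account for the pattern, because without the suffix the lowest Iso PD1-KLRG1- library had 6.32% of counts on ribosomal protein genes and the highest Tri PD1-KLRG1- library 3.75%. A biological effect of the treatment on these cells stays open as a hypothesis, and so does poorer recovery of short transcripts. Other differences in library preparation stay open too and were not tested.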

How the results depend on the processing

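The results with genes of at least 50 CPM, genes detected as a covariate, sample weights, without 3 libraries that stand apart and without the 4 Iso PD1-KLRG1+ libraries come from choices made after seeing the data. Where no cause is given below, the cause was not tested.

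Neither median-ratio scaling nor a minimum count of 50 changed a total by more than 1.5 times. By direction, median-ratio scaling gave 275 genes higher for KLRG1 in Iso PD1- (174 with TMM), 136 lower for treatment in KLRG1+ (87) and 59 lower for the interaction with treatment (26). The share of called genes that rose was 49.4% for PD1 in KLRG1+ (40.8% with TMM) and 47.9% for PD1 in KLRG1- (39.7%). Of 49 list calls, the sign of the median relative to all genes was kept in 49. Of 213 called named genes, 5 kept their call and direction in every alternative run for them, 3 in the KLRG1 comparison of Iso PD1- cells (Klrg1, Cx3cr1 and Gzmb) and 2 in the PD1 comparison of KLRG1- cells (Gzme and Irf8).

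Among values for named genes, median-ratio scaling left 570 the same, 11 newly called and 14 no longer called, DESeq2 474, 94 and 4, the libraries with the suffix 354, 8 and 172, and genes detected as a covariate 494, 6 and 81.

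Below, KLRG1 in Tri PD1+, in Tri PD1- and in Iso PD1-, PD1 in KLRG1+ and in KLRG1-, and treatment in KLRG1+ and in KLRG1- stand for the 7 comparisons, whose counts were 8, 0, 1218, 169, 219, 855 and 113, with 0 and 505 for the interactions of KLRG1 with PD1 and with treatment.

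DESeq2 called 205 genes for KLRG1 in Tri PD1+, 192 in Tri PD1-, 2326 in Iso PD1-, 706 and 524 for PD1 in KLRG1+ and KLRG1-, 1947 and 373 for treatment in KLRG1+ and KLRG1-, and 197 and 1264 for the interactions. It shared 8, 0, 1178, 166, 216, 816, 112, 0 and 482 genes with the edgeR calls in this order, and was not run for the list tests. In simulated data for PD1 in KLRG1-, 57% of its calls were false (77 genes), against 1 false call with edgeR. This was 1 simulated data set, drawn with the spread per gene that edgeR estimated over all libraries. The setting may favour edgeR, and the share of false DESeq2 calls in the real data is not known. Limma-voom with an animal as random block called 124 for KLRG1 in Tri PD1+, 4 in Tri PD1-, 370 and 624 for PD1, 286 for treatment in KLRG1-, and 4 and 240 for the interactions. With sample weights it called 23 and 27 for KLRG1 in Tri PD1+ and PD1-, 13 in Iso PD1-, 547 and 2018 for PD1, 5 and 1098 for treatment, and 5 and 0 for the interactions.

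Without a count filter, counts were 50 and 39 for KLRG1 in Tri PD1+ and PD1-, 334 and 390 for PD1, 251 for treatment in KLRG1- and 46 for the interaction with PD1. Among genes with a mean of at least 50 CPM they were 5 for KLRG1 in Tri PD1+, 491 in Iso PD1-, 179 and 172 for treatment in KLRG1+ and KLRG1- and 57 for the interaction with treatment, with fewer genes tested. With genes detected as a covariate they were 0 for KLRG1 in Tri PD1+, 226 in Iso PD1-, 447 and 42 for treatment and 119 for the interaction with treatment. The labels do not tie replicate numbers to a mouse. Pairing was examined by correlating what remained of log2 CPM after group means and the name series were removed, over 6405 genes. Of 31 same-number pairs of libraries, 13 correlated above 0.1 in these residuals, among them all 6 of Tri replicate 4 (0.156 to 0.523). The median was 0.0561, against -0.017 for other numbers, and 12 of 27 libraries correlated best with their own number, so that pairing in part of the libraries stays open. With a replicate block, counts were 5 for KLRG1 in Tri PD1+ and 277 for the interaction with treatment, and the correlations across genes 0.389 for PD1 and 0.11 for treatment.

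Without the name-series term, counts were 5 for KLRG1 in Tri PD1+ and 68 for treatment in KLRG1-, with correlations of 0.374 for PD1 and 0.109 for treatment. Libraries without the suffix gave 41 for KLRG1 in Tri PD1+, 91 for PD1 in KLRG1-, 497 and 60 for treatment in KLRG1+ and KLRG1-, and 298 for the interaction with treatment. Those with it, 1 or 2 per group, for which a lone library is assumed to vary like the other groups, gave 0 for KLRG1 in Tri PD1+, 1994 in Iso PD1-, 1 and 7 for PD1, 2107 and 0 for treatment, 1662 for the interaction with treatment and 25 list calls. Fits of the compared groups alone gave 2 and 3 for KLRG1 in Tri PD1+ and PD1-, 803 for PD1 in KLRG1-, 0 for treatment in KLRG1+ (edgeR, against 855 in the fit of all libraries) and 277 for the interaction with treatment. An estimated correlation between genes left 16 list calls of 49, and genes detected as a covariate 36. Genes with a mean of at least 50 CPM, libraries without the suffix and leaving out 3 libraries that stand apart each left 40. Among the 16 calls, fry gave an adjusted p under 0.05 in all but homing for KLRG1 in Iso PD1- (0.51). Of the calls with the fixed correlation only, some had no fry call, such as proliferation for KLRG1 in Iso PD1- (0.994) and Tri PD1+ (0.43) and heat shock for treatment in KLRG1+ (0.905). Others had a fry call, such as the stem-like list for PD1 in KLRG1+ (0.0026). The direction of the fry tests was not compared. A minimum count of 50 gave correlations across genes of 0.119 for KLRG1 in Tri PD1- with Iso PD1- and 0.483 for PD1 in both gates.

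Without 3 libraries that stand apart, counts were 16 for KLRG1 in Tri PD1+, 1949 in Iso PD1-, 359 and 341 for PD1, 1404 and 217 for treatment and 1090 for the interaction with treatment. Without the 4 Iso PD1-KLRG1+ libraries they were 1 for KLRG1 in Tri PD1-, 475 and 538 for PD1 and 302 for treatment in KLRG1-.

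Values of named genes changed sign as follows. In libraries with the suffix the log2 fold changes were -10.2 (Pdcd1: KLRG1+ vs KLRG1- in Iso PD1-), -0.11 (Itgb2: KLRG1+ vs KLRG1- in Iso PD1-), -0.398 (Mcm6: KLRG1+ vs KLRG1- in Iso PD1-), -0.998 (Hk1: KLRG1+ vs KLRG1- in Iso PD1-), 10.4 (Pdcd1: Tri vs Iso in PD1-KLRG1+) and 10.2 (Bub1: Tri vs Iso in PD1-KLRG1+). The same Hk1 value was -0.0178 with genes detected as a covariate. The value for Gzmc: Tri vs Iso in PD1-KLRG1+ was -3.61 with all libraries, 9.05 in libraries without the suffix and 9 without 3 libraries that stand apart. Leaving out each library in turn it ran from -4.33, without Iso PD1-KLRG1+ replicate 1, to 8.93, without Iso PD1-KLRG1+ replicate 4.

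Leaving out each library in turn, counts ran from 0 to 8 for KLRG1 in Tri PD1+ (8 only without Tri PD1+KLRG1+ replicate 4), 0 to 1 in Tri PD1-, 883 to 1591 in Iso PD1-, 84 to 158 and 129 to 177 for PD1 in KLRG1+ and KLRG1-, 578 to 1280 and 28 to 154 for treatment in KLRG1+ and KLRG1-, 0 to 1 and 318 to 866 for the interactions, and 44 to 50 for list calls. The lowest and highest came without Iso PD1-KLRG1- replicate 2 and Iso PD1-KLRG1+ replicate 1 (883, 1591), Tri PD1-KLRG1+ replicate 1 and Tri PD1+KLRG1+ replicate 4 (84, 158), Tri PD1+KLRG1- replicates 3 and 5 (129, 177), Tri PD1-KLRG1+ replicate 4 and Iso PD1-KLRG1+ replicate 2 (578, 1280), Iso PD1-KLRG1- replicates 2 and 4 (28, 154), and Iso PD1-KLRG1- replicate 2 and Iso PD1-KLRG1+ replicate 2 (318, 866).

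Depth and spread limit what could be seen. In simulated data at these sample sizes, edgeR found 0% to 4.48% of genes changed 2-fold, 5.97% to 23.9% of those changed 4-fold and 15.2% to 37.9% of those changed 8-fold, so that a gene without a call is not shown to be unchanged, and genes near the floor in the library of 93198 counts are the least covered. Of 20 random lists per simulated comparison, an unadjusted camera p under 0.05 came up in 2 for treatment in KLRG1-, in 1 for KLRG1 in Tri PD1+ and in none elsewhere, where chance gives 1. The list with planted changes was missed for KLRG1 in Iso PD1- at this limit and found in the others. Simulated genes were drawn independently, so neither result covers lists of correlated genes, such as proliferation with an estimated correlation of 0.435.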

Other observations

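The test on the interferon-inducible GTPases and all gene families were chosen only after the result was seen.

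In PD1+ cells of Tri tumours, families of lymphocyte and interferon-linked genes were lower than in PD1- cells, under TMM, median-ratio and DESeq2 scaling alike. The GIMAP family, GTPases of lymphocyte survival, had all 8 measured members negative in both KLRG1 gates, with a median log2 fold change of -0.70 in KLRG1- and -0.68 in KLRG1+ cells (4 and 3 called lower, adjusted p with an estimated correlation 0.000653 and 0.00905). The Schlafen family, growth regulators of T cells, had medians of -0.45 and -1.04 (2 of 7 called lower in each, 0.0164 and 0.00905), and the Ifi200 family of DNA sensors medians of -1.38 and -0.98 (5 and 0 of 10 called lower, 0.0013 and 0.0247).

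In PD1-KLRG1- cells, 3 of 5 translation elongation factors were lower under Tri beside the ribosomal protein genes (median -1.36, adjusted p with an estimated correlation 0.0409), while GIMAP genes had a median of 0.20 (1 of 8 higher, 0.0408) and interferon-inducible GTPases of 0.57 (0 of 18 called with edgeR, 0.0408). In Iso cells, ribosomal protein genes were lower in KLRG1+ than in KLRG1- libraries (74 of 88 called lower, median -1.64), without a call with an estimated correlation (0.398). MHC class I genes had medians near 0 in both PD1 comparisons (-0.09 in KLRG1+ and -0.06 in KLRG1- cells), with a sign that flips under median-ratio scaling. Of 13 members, 2 were called lower in KLRG1+ and 0 in KLRG1- cells.

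A hypothesis was that the lower interferon-stimulated genes of PD1+ cells extend to genes that interferon gamma induces. The 18 interferon-inducible GTPases had a median log2 fold change of -1.25 in KLRG1- cells (17 negative, 8 called) and -1.04 in KLRG1+ cells (16 negative, 4 called), below the lower limit of sets matched on expression (-0.29 and -0.34). This is consistent with a lower response to interferon in PD1+ cells, but these genes answer to both kinds of interferon, the fixed list was lower in the same libraries, and less exposure, less signalling or a different origin of the cells could each give it.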
